A study of Sus scrofa with 36 samples.

How the data were processed

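RNA was sequenced from the left ventricle of 24 pigs. Of these, 12 had permanent ligation of coronary branches and 12 had sham surgery, at 2 days of age (called Young here) or 14 days of age (called Old). Hearts were taken 1 day (Early) or 1 week (Late) after surgery. Each infarcted pig gave 1 library from the infarct zone (IZ) and 1 from the border zone (BZ), and each sham pig gave 1 library from the anterior left ventricular wall, which makes 36 libraries in 12 groups of 3.

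Per the labels' protocols, polyA RNA was made into stranded TruSeq libraries and read as 76 bp pairs on a NextSeq sequencer. Per the submitters' processing notes, bcl2fastq 2.19.0.316, Trimmomatic 0.36, STAR and featureCounts from Subread 1.5.1 were used on the reads. Neither these notes nor the file headers name the genome build, the annotation release or the strand setting of the counting, so genes that overlap or share reads with a near-identical copy are uncertain. The deposited values are raw counts per gene, whole numbers with no normalization, per the file headers and the values themselves.

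The table holds 25880 Ensembl pig gene identifiers, and no gene symbols. A reference table of pig gene names gave a symbol for 14857 of them. Library totals ran from 8.1 to 39.8 M counts with a median of 22.55 M. Genes with few counts were removed with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 14537 genes over all 36 libraries, 12165 of them with a symbol. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood, robust spread) in R 4.3.3, with 1 mean per group and 24 residual degrees of freedom. The IZ and BZ of a pig enter this fit as independent. IZ and BZ were each compared with the sham group of the same age and time. Differences between responses (Old minus Young, and Late minus Early) and differences between sham groups came from the same fit. IZ was compared with BZ of the same pigs in a fit over the 24 libraries of infarcted pigs with the animal as a block, which left 8 residual degrees of freedom and 14386 genes. Each of the 22 comparisons was adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Values are log2 fold changes ± the standard error (SE) of the fit, with 3 libraries per group. Counting error limits the precision of genes with few counts.

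Before the data were examined, the comparisons, the alternatives, 27 gene lists and a rule for the genes named in the text were fixed. Of 566 list members, 489 were found by symbol. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. Members past the threshold are counted as called over all genes tested, and also adjusted over the list alone. Where a list has members with no count in a group, its median was also computed with those members at their bound (a floor of 3 counts over the group). The naming rule takes from each comparison the 5 called genes with the largest rise and the 5 with the largest fall, among genes with a symbol and a mean log2 CPM of at least 1, and where 2 groups of 3 are compared with no overlap between their libraries. It adds from each list the 2 called members with the largest absolute log2 fold change and a mean log2 CPM of at least 0, and a panel of 30 genes, of which 25 are in the table. The genes printed in the text are a part of those the rule names. That part was chosen after seeing their values and whether each call held without each library in turn, with genes whose call held preferred, so the number of named genes that kept their call is given for each comparison. Chance gives no overlap between 3 and 3 libraries for 10% of unchanged genes.

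The lists cover the cell cycle, the cardiomyocyte sarcomere, cardiac stress genes, cardiac channels and transcription factors, fatty acid oxidation, nuclear and mitochondrially encoded respiratory genes, glycolysis, hypoxia, acute inflammation, macrophages, lymphocytes, the interferon response, immediate early genes, heat shock and endoplasmic reticulum stress, extracellular matrix, fibroblasts, endothelium, smooth muscle, epicardium, skeletal muscle, atrium, red blood cells, adipocytes, Schwann cells, fetal growth genes and YAP signalling.

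The alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 test, no count filter, a fit of the compared groups alone, library preparation batch as a term, RNA integrity as a covariate, a further minimum log2 fold change of 1, limma-voom with the animal as a random replicate block, mitochondrially encoded genes left out, and each library left out in turn. For IZ against BZ, the animal block was also dropped, and for Old Late the animal of BZ replicate 3 was also taken from a conflicting label. A further pair of alternatives was chosen after seeing the data: a term for the sex of the pig as read from the Y-linked gene EIF1AY, and a fit without 2 libraries, Young Early BZ replicate 2 and Young Late Sham replicate 2.

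Preparation batch 1 holds all Young Early libraries, batch 2 all Old Early libraries and batch 3 all Old Late libraries, while Young Late libraries lie in batches 1 and 2. Batch 3 therefore cannot be separated from the Old Late groups. The pairing of IZ and BZ was checked by correlating the deviations of libraries from their group means. The pairs come from the animal numbers in the labels. Of the 12 pairs, 9 correlated above 0.1 (0.45 to 0.67), the 3 Young Late pairs lay between −0.2 and −0.04, and pairs from different pigs of a condition had a median of −0.2. Deviations from a mean of 3 are tied to one another, so these correlations are not independent. A further check, chosen after seeing the data, took 100 genes that separated pigs and agreed between zones in the other 3 conditions, and the median absolute log2 distance of each BZ library to the IZ libraries of its condition. In all 12 pairs both libraries gave the same reading of the Y-linked gene EIF1AY, present or absent. No 2 libraries of a group were copies of one another (36 pairs, lowest chi-square per degree of freedom 11.01).

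The same libraries were also regrouped and refitted, over 10 splits of 3 against 3, 4 splits of the paired zones, and 100 of 200 regroupings for each difference between responses. The fits were tested on simulated data drawn from the real means and library sizes, with 200 changed genes. For IZ against sham in Young Early, edgeR recovered 33% of genes changed 2-fold and 96% of genes changed 4-fold among 14237 genes, with 7 false calls. For the Early IZ response by age, it recovered 10% and 74%, with 7 false calls. DESeq2 made 20 false calls where edgeR made 7 for the first of these comparisons. In each of 18 comparisons of simulated unchanged groups, edgeR made 0 false calls.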

Results

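The data are counts per gene from the left ventricle of 24 pigs, as 36 libraries in 12 groups of 3. Infarcts were made, or sham surgery done, at 2 days (Young) or 14 days of age (Old), and tissue was taken 1 day (Early) or 1 week (Late) later, so that pigs were 3, 15, 9 and 21 days old at harvest in the Young Early, Old Early, Young Late and Old Late groups. The design asks how the infarct zone (IZ) and the border zone (BZ) respond in a heart of each age, and whether the responses differ by age at injury. All changes are log2 fold changes ± SE of the edgeR quasi-likelihood fit with n = 3 libraries per group, and rose, fell and changed are used of genes with a Benjamini-Hochberg adjusted p under 0.05. Camera p-values use a preset correlation between genes, and those marked estimated use a correlation estimated from the data.

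The first principal component held 34.5% of the variance between libraries and the second 21%. Mitochondrially encoded genes took from 9.8% to 44.1% of a library's counts, with a mean of 10.5% ± 0.611 (SD, n = 3) in Old Late IZ and 23.4% ± 0.6 in Old Late Sham. RNA integrity numbers ran from 6.3 to 8.4. Young Early BZ replicate 2, at 39.8 M counts, lay farthest from its group, and Young Late Sham replicate 2 had the lowest total, at 8.1 M.

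**Figure D1:**
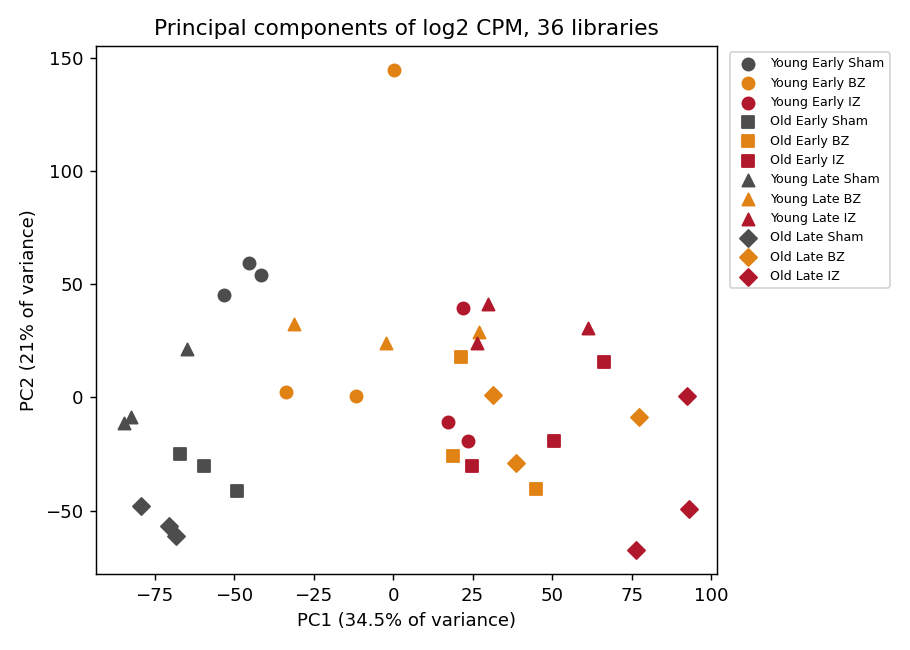
Each point is 1 of the 36 libraries on the first (34.5% of the variance) and second (21%) principal components of log2 counts per M. Color and shape give the age, time and zone of the library.

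**Figure D2:**
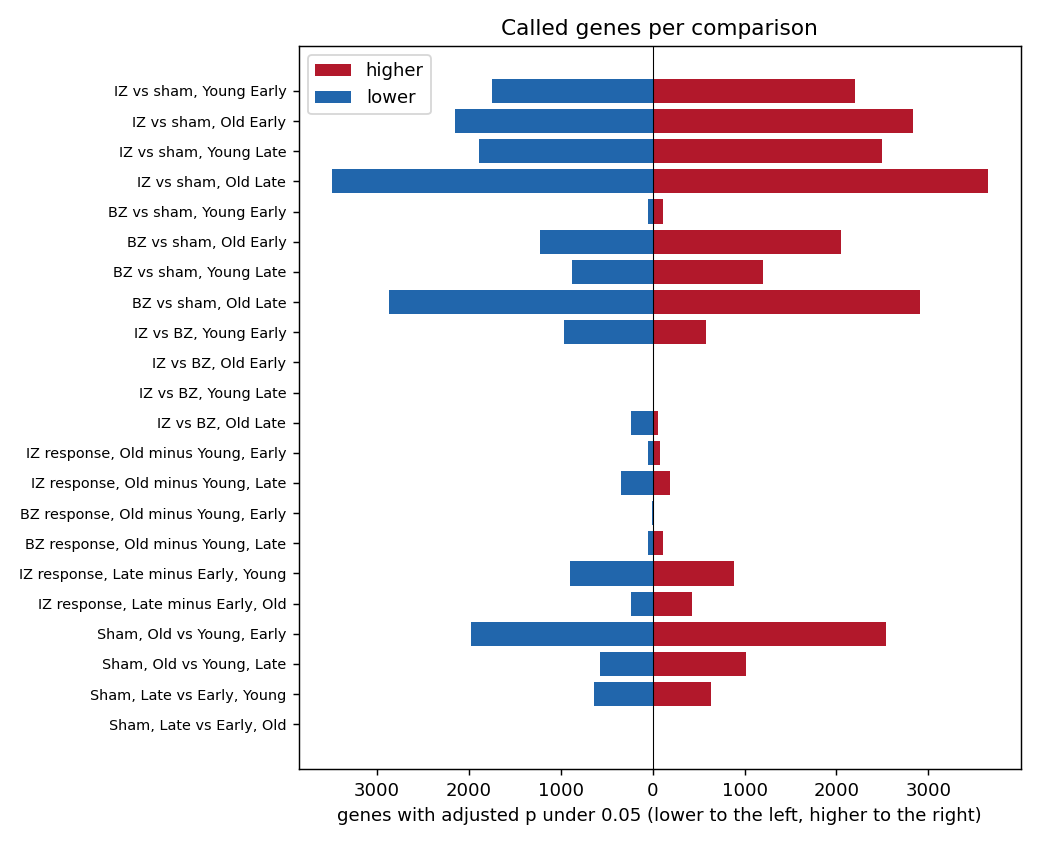
Bars give the number of genes with an adjusted p under 0.05 in each of 22 comparisons, lower to the left and higher to the right. The IZ of Old Late pigs against sham has the longest bars, with 3646 genes higher and 3491 lower.

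The first comparison asks which genes respond in the IZ 1 day after an infarct on day 2 of life. In Young Early IZ the matrix glycoprotein TNC rose by 5.20 ± 0.70 against sham, the matrix and immune signal SPP1 by 5.32 ± 0.97 and the monocyte attractant CCL2 by 3.67 ± 0.47. HK2, which starts glycolysis, rose by 4.26 ± 0.72, the endoplasmic reticulum chaperone HSPA5 by 2.60 ± 0.26 and the DNA replication gene MCM6 by 1.92 ± 0.29. The lipid droplet protein PLIN5 fell by 3.37 ± 0.47, the heart actin ACTC1 by 1.93 ± 0.47 and CPT1B, which moves fatty acids into mitochondria, by 1.84 ± 0.29. For each of these 9 genes all 3 IZ libraries lay on 1 side of all 3 sham libraries. Of 36 nuclear oxidative phosphorylation genes 36 fell (36 adjusted over the list alone), with a median of −1.21 and a camera adjusted p = 1.43e-22 (0.0856 estimated). Of 20 sarcomere and calcium handling genes 16 fell and 0 rose (18 fell adjusted over the list alone), with a median of −1.40 and a camera adjusted p = 6.33e-13 (0.0614 estimated). Of 20 acute inflammation genes 15 rose (17 adjusted over the list alone). Their median was 3.55, or 3.50 with absent members at their bound, with a camera adjusted p = 4.43e-11 (0.0614 estimated). Heat shock and endoplasmic reticulum stress genes rose in 16 of 18 cases (16 adjusted over the list alone), with a median of 1.23 and a camera adjusted p = 6.39e-13 (0.0614 estimated). Of 38 cell cycle genes 9 rose and 0 fell (9 adjusted over the list alone), with a median of 0.73, or 0.46 without Young Early IZ replicate 3, and a camera adjusted p = 0.00198 (0.609 estimated). CDK1 and TOP2A did not pass (0.70 ± 0.48 and 0.84 ± 0.38). edgeR called 3956 genes, 2207 higher and 1749 lower, against 2628 without Young Early Sham replicate 1 and 2304 without Young Early IZ replicate 3. Of the 61 called genes that the naming rule gives here, 45 kept the call without each of the 6 libraries in turn.

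The same question in pigs infarcted at 14 days brought neutrophil, matrix and vessel genes. In Old Early IZ the neutrophil growth factor receptor CSF3R rose by 5.70 ± 0.72, CCL2 by 5.05 ± 0.50, the protease inhibitor TIMP1 by 6.47 ± 0.72 and TNC by 6.71 ± 0.75. COL1A1 rose by 2.193 ± 0.37 and the endothelial genes SOX18 and ENG by 1.85 ± 0.29 and 1.75 ± 0.31. Creatine kinase CKM fell by 2.31 ± 0.43 and the fatty acid enzyme ACAA2 by 2.04 ± 0.29. In all 9 genes the 3 IZ libraries lay on 1 side of the 3 sham libraries. All 20 acute inflammation genes rose (20 adjusted over the list alone). Their median was 5.04, or 4.96 with absent members at their bound, with a camera adjusted p = 6.18e-16 (0.0761 estimated). Of 35 extracellular matrix genes 28 rose (29 adjusted over the list alone), with a median of 1.74 and a camera adjusted p = 5.4e-15 (0.0987 estimated). Of 14 endothelial genes 10 rose and 0 fell (10 adjusted over the list alone), with a median of 1.06 and a camera adjusted p = 1.95e-05 (0.148 estimated). Of 25 fatty acid oxidation genes 19 fell (20 adjusted over the list alone). Their median was −1.24, with a camera adjusted p = 8.89e-11 (0.0761 estimated). Of 22 interferon response genes 15 fell (16 adjusted over the list alone), with a median of −1.60 and a camera adjusted p = 0.000534 (0.389 estimated), but −0.32 and a camera adjusted p = 0.26 without Old Early Sham replicate 3. The cell cycle list had a median of −0.04, a mean of 0.10 and an upward camera test that did not pass, with 5 genes higher and 1 lower of 38 (5 and 0 adjusted over the list alone). edgeR called 4988 genes, 2838 higher and 2150 lower, against 3258 without Old Early IZ replicate 1. Of 72 named called genes 54 kept the call without each of the 6 libraries.

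By 1 week the IZ of pigs infarcted at 2 days combined matrix, macrophage and cell division genes. In Young Late IZ the cartilage matrix protein CILP rose by 6.14 ± 0.55, SPP1 by 7.04 ± 1.08, the collagen regulator CTHRC1 by 5.77 ± 0.74 and COL1A1 by 2.87 ± 0.38. CDK1, the kinase that drives mitosis, rose by 2.16 ± 0.48 and TOP2A, which untangles DNA, by 1.68 ± 0.39. The fetal muscle genes MYL4 and ACTA1 rose by 3.78 ± 0.77 and 1.77 ± 0.35. The calcium pump gene ATP2A2 fell by 2.17 ± 0.49 and the potassium channel subunit KCNIP2 by 2.31 ± 0.41. For each of these 10 genes the 3 IZ libraries lay on 1 side of the 3 sham libraries. All 23 macrophage genes rose (23 adjusted over the list alone), with a median of 3.57 and a camera adjusted p = 2.93e-23 that held with an estimated correlation (0.0397). Among 35 extracellular matrix genes, 31 rose (32 adjusted over the list alone). Their median was 2.12, with a camera adjusted p = 6.45e-24 that also held (0.0397). Among 38 cell cycle genes, 30 rose and 0 fell (31 adjusted over the list alone), with a median of 1.59 and a camera adjusted p = 3.12e-11 (0.32 estimated). Cell cycle levels differed between the sham libraries, at 4.325 log2 CPM in replicate 1, 3.189 in replicate 2 and 2.422 in replicate 3, while the Young Late IZ mean was 4.964 ± 0.156 (SD, n = 3). Among 14 endothelial genes, 7 fell (1 rose and 8 fell adjusted over the list alone), with a median of −0.66 and a camera adjusted p = 0.0187 (0.416 estimated), but −0.40 and a camera adjusted p = 0.0862 without Young Late Sham replicate 2. edgeR called 4390 genes, 2499 higher and 1891 lower, against 2807 without Young Late IZ replicate 1. Among 70 named called genes, 50 kept the call without each of the 6 libraries.

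In pigs infarcted at 14 days the genes called in the IZ at 1 week included matrix genes, which rose, and muscle and metabolic genes, which fell. In Old Late IZ COL11A1 rose by 7.62 ± 0.66, CTHRC1 by 7.96 ± 0.74, the fibroblast adhesion protein POSTN by 5.39 ± 0.66 and COL1A1 by 4.58 ± 0.42. MYOM2 fell by 4.85 ± 0.70, PLIN5 by 4.57 ± 0.52, PPARGC1A by 2.81 ± 0.30 and the heavy chain MYH6 by 1.90 ± 0.24. MYH7 had no entry, so the isoform was uncertain. In all 8 genes the 3 IZ libraries lay on 1 side of the 3 sham libraries. All 35 extracellular matrix genes rose (35 adjusted over the list alone). Their median was 3.68, with a camera adjusted p = 1.07e-30 that held with an estimated correlation (0.0168). All 19 fibroblast genes rose (19 adjusted over the list alone), with a median of 3.40 and a camera adjusted p = 1.16e-16 that held too (0.0155). Among 36 nuclear oxidative phosphorylation genes, 34 fell (36 adjusted over the list alone), with a median of −1.51 and a camera adjusted p = 1.25e-15 (0.193 estimated). All 13 mitochondrially encoded genes fell (13 adjusted over the list alone). Their median was −1.78, with a camera adjusted p = 0.000181 (0.351 estimated). With 38 cell cycle genes measured, 14 rose (14 adjusted over the list alone), with a median of 0.92 and a camera adjusted p = 0.00453 (0.714 estimated). That median was 0.59, with a camera adjusted p = 0.0557, without Old Late Sham replicate 3 and 1.62 without Old Late Sham replicate 2. CDK1 and TOP2A did not pass (0.97 ± 0.46 and 0.45 ± 0.37). edgeR called 7137 genes, 3646 higher and 3491 lower. Of 73 named called genes 63 kept the call without each of the 6 libraries.

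**Figure D3:**
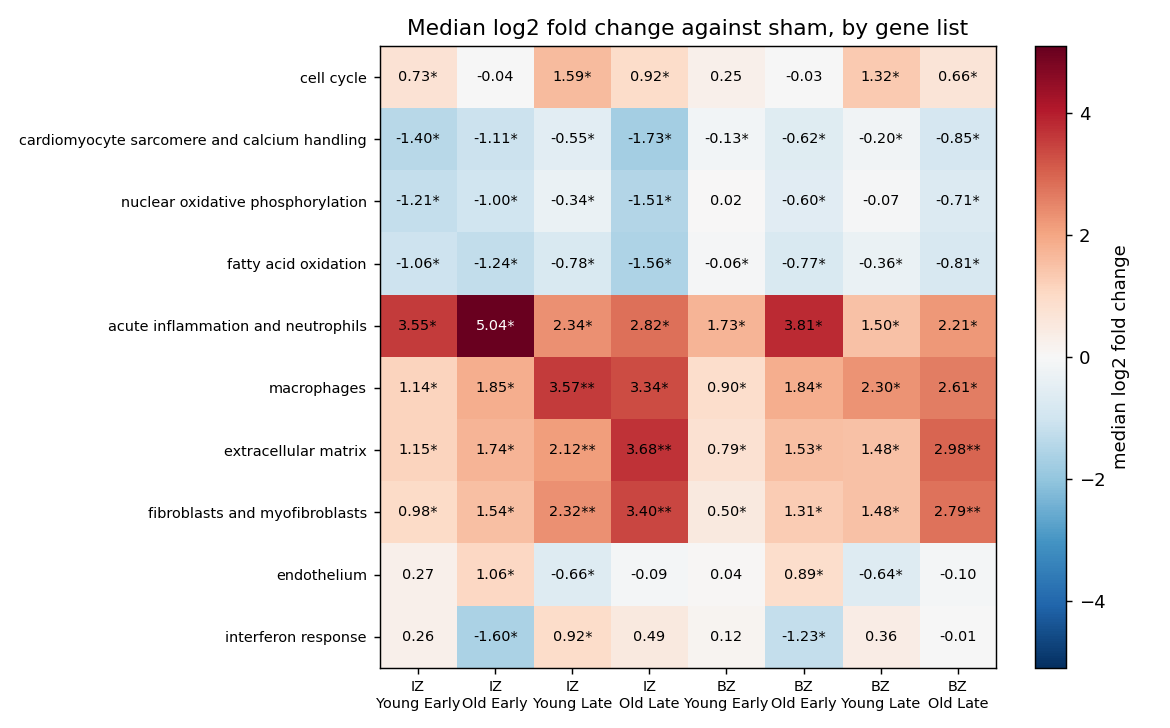
Each cell gives the median log2 fold change against sham of the measured members of a gene list, for the IZ and the BZ of each group of pigs. A star marks a camera adjusted p under 0.05 at a preset correlation of 0.01, and a second star marks that the call held with an estimated correlation, as for the extracellular matrix list in Old Late IZ (3.68).

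The difference between ages was tested as the IZ response of Old pigs minus that of Young pigs. Early after injury, the endothelial chemokine receptor ACKR1 had a response higher in Old pigs by 3.80 ± 0.84, the membrane protein TSPAN15 by 2.48 ± 0.45, SOX18 by 1.90 ± 0.40 and ENG by 1.89 ± 0.43. Responses of the phosphodiesterase PDE3A and the antiviral gene IFIT5 were lower, at −2.98 ± 0.63 and −1.79 ± 0.44. These calls lay close to the threshold, with an adjusted p = 0.0282 for TSPAN15 and 0.0493 for each of the other 5. Part of each difference lay in the shams, where Old minus Young was −2.01 for TSPAN15, −0.91 for SOX18, −1.07 for ENG, 2.69 for PDE3A and 1.98 for IFIT5, all called, and −1.68 for ACKR1, which was not. With 14 endothelial genes measured, 2 had a higher response in Old pigs (6 adjusted over the list alone), with a median of 0.79 and a camera adjusted p = 0.000324 (0.66 estimated). That median was 0.43 without Old Early IZ replicate 3. With 35 extracellular matrix genes measured, 2 had a higher response (6 adjusted over the list alone). Their median was 0.62, or 0.60 with absent members at their bound, with a camera adjusted p = 0.000613 (0.685 estimated). Among 22 interferon response genes, 1 had a lower response (7 adjusted over the list alone), with a median of −1.66 and a camera adjusted p = 0.000219 (0.685 estimated), but −0.64 and a camera adjusted p = 0.183 without Old Early Sham replicate 3. The cell cycle list had a median of −0.66 with 0 genes called (0 adjusted over the list alone) and a camera adjusted p = 0.00909 (0.722 estimated), which was lost without Young Early IZ replicate 3 (−0.40, camera adjusted p = 0.0525) and without Young Early Sham replicate 3 (−0.52, camera adjusted p = 0.0576). edgeR called 133 genes, 78 higher and 55 lower, while limma-voom with the animal as a random block called 0 (3581 at an unadjusted p under 0.05), DESeq2 934, edgeR on the compared groups alone 1444, without a count filter 5 and with sex as a term 303. The count was 679 without Young Early IZ replicate 2, 1487 without Old Early IZ replicate 2, 2 without Old Early Sham replicate 1, 1 without Young Early Sham replicate 2 or Young Early IZ replicate 1, and 0 without Young Early Sham replicate 1 or 3, Young Early IZ replicate 3, Old Early Sham replicate 2 or 3, or Old Early IZ replicate 1 or 3. With preparation batch as a term it was 5, and with RNA integrity as a covariate 0 (1342 at an unadjusted p under 0.05). None of the 18 named called genes kept the call in all 12 of these fits, and ACKR1, TSPAN15, SOX18, ENG, PDE3A and IFIT5 kept it in 2. Of 100 regroupings of the same libraries, the real one included, 8 gave as many called genes.

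At 1 week the genes called for the age difference in the IZ included energy, muscle and matrix genes. The mitochondrial creatine kinase CKMT2 had a response lower in Old pigs at −2.23 ± 0.40, the nutrient sensing gene RRAGD at −2.31 ± 0.32, ACTA1 at −2.65 ± 0.48 and PPARGC1A at −2.03 ± 0.41. The vesicle transport gene SYTL2 had a higher response, by 3.07 ± 0.61, and so had FN1, by 5.29 ± 1.27. Both may lie partly in shams, as at least 3 other differences did. Sham Old minus Young was 1.63 for ACTA1, 1.22 for PPARGC1A and 0.87 for RRAGD, with age and RNA quality mixed. Mean CPM in Old and Young Late IZ was 5120 and 10330, 24.88 and 43.75, and 29.05 and 78.95. The calls of CKMT2, RRAGD, ACTA1 and SYTL2 held without each of the 12 libraries. That of PPARGC1A ended without Old Late IZ replicate 3 (value range −2.36 to −1.73), and that of FN1 (range 3.61 to 5.80) without Old Late IZ replicate 3, Old Late Sham replicate 1 or 2, Young Late IZ replicate 2 or 3, or Young Late Sham replicate 2. With 36 nuclear oxidative phosphorylation genes measured, 13 had a lower response in Old pigs (25 adjusted over the list alone), with a median of −1.15 and a camera adjusted p = 3.28e-19 (0.151 estimated). Of 35 extracellular matrix genes 7 had a higher response (23 adjusted over the list alone). Their median was 1.57, with a camera adjusted p = 1.22e-16 (0.135 estimated). Of 19 fibroblast genes 5 had a higher response (9 adjusted over the list alone), with a median of 1.09 and a camera adjusted p = 6.31e-08 (0.135 estimated). Of 20 sarcomere genes 3 had a lower response (4 adjusted over the list alone), with a median of −1.001 and a camera adjusted p = 9.68e-09 (0.135 estimated). The macrophage list had a median of −0.02, a mean of −0.03 and an upward camera test that did not pass, with 0 genes called by edgeR. edgeR called 533 genes, 191 higher and 342 lower, and 5 of 28 named called genes kept the call in all 12 fits. The majority turned without mitochondrially encoded genes (253 higher, 169 lower) and in a fit of the compared groups alone (462 and 338), and was small with DESeq2 (507 and 554), against 106 and 327 by limma-voom. The count was 124 and 43 without Young Late IZ replicates 2 and 3, 84 without Young Late Sham replicate 2, 176 and 87 without Old Late IZ replicates 1 and 3, and 173 and 159 without Old Late Sham replicates 1 and 2. Of 100 regroupings 6 gave as many called genes, and every Old Late library belongs to preparation batch 3, which holds no other group.

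The cell cycle list, with a median of 1.59 in Young Late IZ and 0.92 in Old Late IZ against sham, did not hold as a difference between ages. Of its 38 genes 0 had a called difference (0 adjusted over the list alone), the median was −0.51 and the camera adjusted p = 0.00522 (0.723 estimated). The median was 0.10 (camera adjusted p = 0.595) without Old Late Sham replicate 2, −0.17 (camera adjusted p = 0.54) without Young Late Sham replicate 3 and −0.24 (camera adjusted p = 0.0573) without Old Late IZ replicate 2. With the call kept, it was −1.40 without Young Late Sham replicate 1, −0.82 without Old Late Sham replicate 3, −0.30 without Young Late IZ replicate 1 and −0.31 without Young Late Sham replicate 2. Mean levels of the list were 3.312 ± 0.958 log2 CPM (SD, n = 3) in Young Late Sham and 3.188 ± 0.794 in Old Late Sham, against 4.964 ± 0.156 in Young Late IZ and 4.141 ± 0.296 in Old Late IZ.

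**Figure D4:**
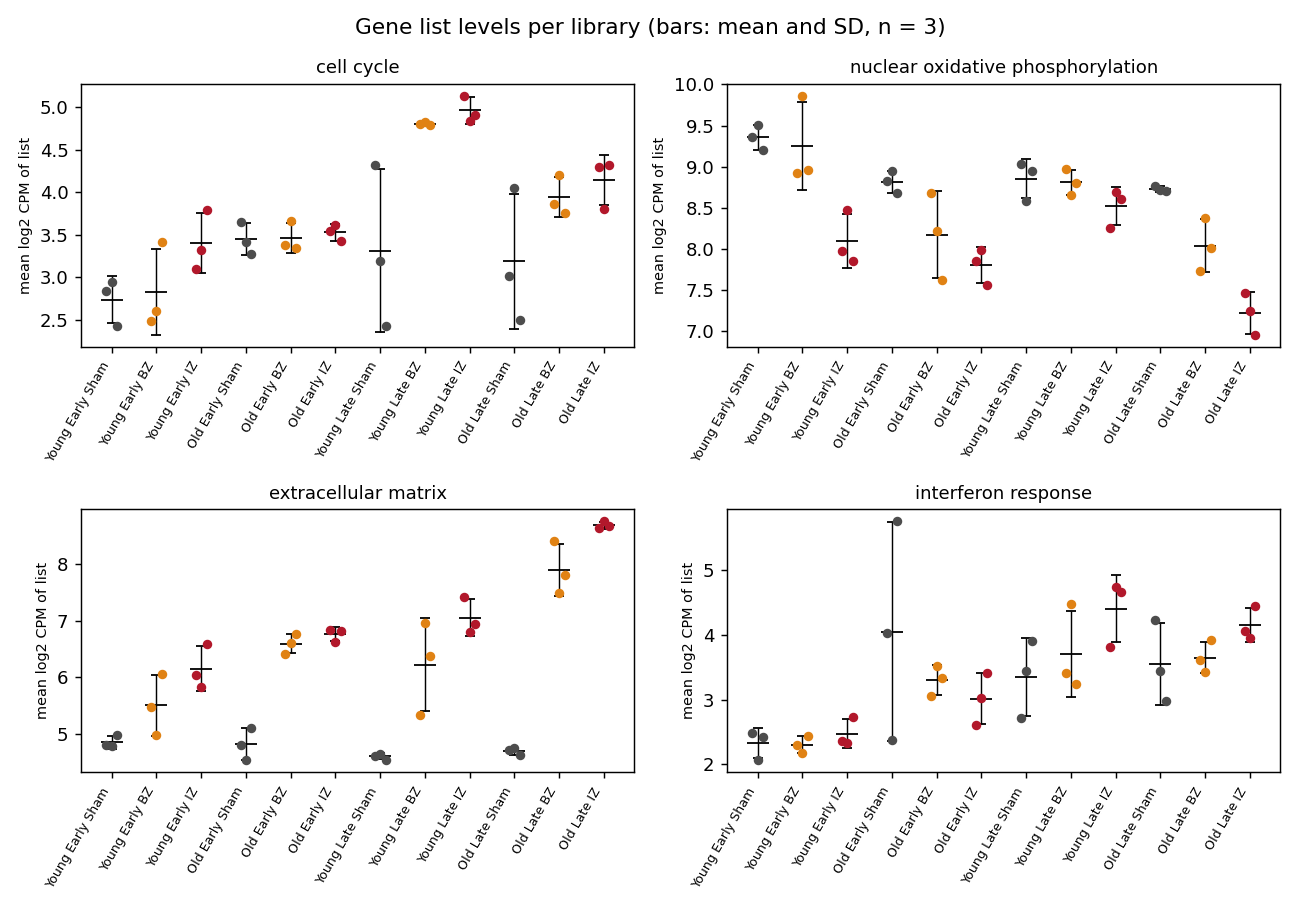
Each point is the mean log2 CPM of a gene list in 1 library, for 4 lists and 12 groups, with a bar for the mean and whiskers for the SD of the 3 libraries. The Late sham groups spread widely in the cell cycle list (SD 0.958 and 0.794), and Old Early Sham in the interferon response list (SD 1.693).

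The BZ comparisons ask what responds beside the infarct. In Young Early BZ the calcium binding protein S100A6 rose by 3.38 ± 0.53 and CCL2 by 2.82 ± 0.46, with all 3 BZ libraries above all 3 shams, and these were the 2 of 20 named called genes whose call held without each of the 6 libraries. Among 20 acute inflammation genes, 3 rose (6 adjusted over the list alone). Their median was 1.73, or 1.56 with absent members at their bound, with a camera adjusted p = 1.05e-08 (0.256 estimated). That median was 2.77 without Young Early Sham replicate 1. Of 18 heat shock and endoplasmic reticulum stress genes 5 rose (14 adjusted over the list alone), with a median of 0.73, or 0.43 without Young Early BZ replicate 2, and a camera adjusted p = 2.86e-11 (0.11 estimated). Among 35 extracellular matrix genes, 3 rose (10 adjusted over the list alone), with a median of 0.79 and a camera adjusted p = 2.09e-06 (0.55 estimated). edgeR called 162 genes, 114 higher and 48 lower. The count was 11, 43 and 12 without Young Early Sham replicates 1, 2 and 3, 979 without Young Early BZ replicate 1 and 299 without Young Early BZ replicate 3. It was 22 by limma-voom, 561 by DESeq2 (334 higher, 227 lower), 27 with RNA integrity as a covariate and 0 by edgeR on the compared groups alone (755 at an unadjusted p under 0.05), and 3 of 10 splits gave as many.

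In Old Early BZ the inflammation gene PTX3 rose by 5.49 ± 0.65, TNC by 6.01 ± 0.73, COL1A1 by 2.25 ± 0.38 and the vessel adhesion gene PECAM1 by 1.52 ± 0.22. The sarcomere gene MYBPC3 fell by 1.46 ± 0.32 and the respiratory chain gene NDUFS1 by 1.24 ± 0.29, and in all 6 genes the 3 BZ libraries lay on 1 side of the shams. Of 23 macrophage genes 22 rose (22 rose and 1 fell adjusted over the list alone). Their median was 1.84, with a camera adjusted p = 4.09e-13 (0.0894 estimated). With 35 extracellular matrix genes measured, 29 rose (30 adjusted over the list alone), with a median of 1.53 and a camera adjusted p = 1.42e-19 (0.0637 estimated). Among 25 fatty acid oxidation genes, 12 fell (15 adjusted over the list alone), with a median of −0.77 and a camera adjusted p = 9.57e-08 (0.0971 estimated). edgeR called 3275 genes, 2045 higher and 1230 lower, against 1967 without Old Early Sham replicate 2. Of 60 named called genes 37 kept the call without each of the 6 libraries.

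In Young Late BZ CILP rose by 5.39 ± 0.54, SPP1 by 5.63 ± 1.03, ACTA1 by 1.85 ± 0.35 and the mitotic genes KIF11 and HMMR by 1.86 ± 0.42 and 1.85 ± 0.42. KCNIP2 fell by 1.85 ± 0.40, and in these 6 genes the 3 BZ libraries lay on 1 side of the shams. Of 38 cell cycle genes 22 rose and 0 fell (32 adjusted over the list alone). Their median was 1.32, or 2.12 without Young Late Sham replicate 1, with a camera adjusted p = 3.96e-16 (0.193 estimated). Among 23 macrophage genes, 19 rose (21 adjusted over the list alone), with a median of 2.30 and a camera adjusted p = 1.6e-18 (0.0954 estimated). Of 35 extracellular matrix genes 24 rose (29 adjusted over the list alone), with a median of 1.48 and a camera adjusted p = 4.71e-19 (0.0954 estimated). edgeR called 2071 genes, 1199 higher and 872 lower (1372 by limma-voom), against 694 and 1098 without Young Late BZ replicates 2 and 3 and 707 and 1284 without Young Late Sham replicates 2 and 3. Among 57 named called genes, 24 kept the call without each of the 6 libraries.

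In Old Late BZ CTHRC1 rose by 7.39 ± 0.73, COL11A1 by 6.44 ± 0.64, CILP by 5.72 ± 0.52 and COL1A1 by 3.93 ± 0.40, while the calcium pump gene ATP2A2 fell by 2.13 ± 0.49 and the cardiac factor TBX20 by 2.65 ± 0.68. For these 6 genes the 3 BZ libraries lay on 1 side of the shams. Among 35 extracellular matrix genes, 33 rose (33 adjusted over the list alone). Their median was 2.98, with a camera adjusted p = 3.67e-32 that held with an estimated correlation (0.0166). Among 19 fibroblast genes, 18 rose (18 adjusted over the list alone), with a median of 2.79 and a camera adjusted p = 2.67e-19 that held too (0.00824). Of 36 nuclear oxidative phosphorylation genes 18 fell (18 adjusted over the list alone), with a median of −0.71 and a camera adjusted p = 2.28e-06 (0.413 estimated). edgeR called 5775 genes, 2905 higher and 2870 lower (3609 with RNA integrity as a covariate), against 3508 without Old Late BZ replicate 1. Of 70 named called genes 58 kept the call without each of the 6 libraries.

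The BZ response was compared between ages in the same way. Early after injury SOX18 had a response higher in Old pigs by 1.94 ± 0.40, and CORIN, which activates natriuretic peptides, a lower one at −2.12 ± 0.42, while the shams differed by −0.91 and 1.58. The call of CORIN ended without Old Early BZ replicate 1 or 2, Old Early Sham replicate 2 or 3, or Young Early Sham replicate 1, and that of SOX18 also without Old Early Sham replicate 1, Young Early BZ replicate 1 or 3, or Young Early Sham replicate 3. With 35 extracellular matrix genes measured, 0 were called over all genes (12 higher adjusted over the list alone). Their median was 0.97, with a camera adjusted p = 2.67e-10 (0.308 estimated). Of 14 endothelial genes 1 had a higher response (9 adjusted over the list alone), with a median of 0.88 and a camera adjusted p = 9.02e-08 (0.266 estimated). The macrophage list had 0 of 23 genes called over all genes (1 adjusted over the list alone), a median of 1.20 and a camera adjusted p = 3.94e-07 (0.347 estimated). The nuclear oxidative phosphorylation list had 0 of 36 genes called over all genes (2 lower adjusted over the list alone), a median of −0.58 and a camera adjusted p = 1.99e-06 (0.561 estimated). That median was −0.12 (camera adjusted p = 0.112) without Young Early BZ replicate 2 and −0.39 without Old Early BZ replicate 3. edgeR called 32 genes, 20 higher and 12 lower (19 by limma-voom, 602 by DESeq2 with 297 higher and 305 lower, and 0 with RNA integrity as a covariate and on the compared groups alone, with 1848 and 1731 at an unadjusted p under 0.05), and 0 of 10 named called genes kept the call in all 12 fits. The count was 2256 without Young Early BZ replicate 2, 53 without Young Early BZ replicate 3, 20 without Young Early BZ replicate 1, 17 without Old Early Sham replicate 1, 9 without Young Early Sham replicate 3, and 0 without Young Early Sham replicate 1, Old Early Sham replicate 2 or 3, or Old Early BZ replicate 1 or 2. Of 100 regroupings 16 gave as many called genes.

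At 1 week the gelatinase MMP2 had a BZ response higher in Old pigs by 2.16 ± 0.43, the collagen crosslinker LOXL1 by 2.14 ± 0.43 and the contractile actin ACTA2 by 2.23 ± 0.52, and of these LOXL1 differed between the shams (−1.07). Each call held in 5 of 12 fits and ended without Old Late BZ replicate 1, Old Late Sham replicate 1, 2 or 3, Young Late BZ replicate 1 or 3, or Young Late Sham replicate 2. Of 35 extracellular matrix genes 4 had a higher response (22 adjusted over the list alone), with a median of 1.49 and a camera adjusted p = 7.88e-19 (0.105 estimated). With 19 fibroblast genes measured, 5 had a higher response (7 adjusted over the list alone). Their median was 1.25, with a camera adjusted p = 2.02e-10 (0.105 estimated). The nuclear oxidative phosphorylation list had 0 of 36 genes called over all genes (1 lower adjusted over the list alone), a median of −0.55 and a camera adjusted p = 6.28e-08 (0.657 estimated). The cell cycle list had 0 of 38 genes called over all genes (3 lower adjusted over the list alone), a median of −0.69 and a camera adjusted p = 0.000327 (0.751 estimated). That median was −0.02 (camera adjusted p = 0.241) without Old Late Sham replicate 2, −0.30 (camera adjusted p = 0.257) without Young Late Sham replicate 3 and −1.35 without Young Late Sham replicate 1. edgeR called 158 genes, 108 higher and 50 lower (4 by limma-voom, 18 with RNA integrity as a covariate, 45 on the compared groups alone, 26 without a count filter, 592 by DESeq2, 392 with sex as a term, and 166 higher and 33 lower without mitochondrially encoded genes), and 0 of 16 named called genes kept the call in all 12 fits. The count was 388 without Young Late BZ replicate 2, 320 without Young Late Sham replicate 3, 21 without Old Late Sham replicate 3, 6 without Young Late BZ replicate 3, 1 without Young Late Sham replicate 2, and 0 without Young Late BZ replicate 1, Old Late BZ replicate 1, or Old Late Sham replicate 1 or 2. Of 100 regroupings 5 gave as many called genes.

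The 2 zones of the same heart were compared with the pig as a block. In Young Early pigs the chaperone HSPA5 was higher in the IZ by 1.62 ± 0.26 and the immediate early gene FOS by 2.36 ± 0.45, while the ventricular light chain MYL2 was lower at −1.81 ± 0.29 and CPT1B at −1.31 ± 0.20. These 4 are among the 12 of 42 named called genes whose call held without each of the 6 libraries. Among 36 nuclear oxidative phosphorylation genes, 34 were lower in the IZ (36 adjusted over the list alone), with a median of −1.14 and a camera adjusted p = 8.9e-38 (0.188 estimated). Among 38 cell cycle genes, 9 were higher (21 adjusted over the list alone), with a median of 0.58 and a camera adjusted p = 2.52e-07 (0.188 estimated). edgeR called 1541 genes in Young Early pigs, 580 higher and 961 lower in the IZ, against 487, 321, 504 and 330 without IZ replicate 1, IZ replicate 2, BZ replicate 1 and BZ replicate 2. It was 355 without the block, 3365 by limma-voom, 2567 by DESeq2 and 0 by edgeR on the compared groups alone (2110 at an unadjusted p under 0.05). In Old Late pigs 13 of 36 nuclear oxidative phosphorylation genes were lower in the IZ (36 adjusted over the list alone). Their median was −0.86, with a camera adjusted p = 1.78e-29 (0.23 estimated). edgeR called 295 genes in Old Late pigs, 63 higher and 232 lower, and 0 without any 1 of the 6 libraries, so that 0 of 23 named called genes kept the call. The labels of BZ replicate 3 disagree on its pig, and with the other number the count was 0 (1494 at an unadjusted p under 0.05). It was 5 without the block, 1011 by DESeq2, 1295 by limma-voom and 1733 on the compared groups alone. In Old Early pigs edgeR called 0 genes, with 928 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom, and 14 without IZ or BZ replicate 3. In Young Late pigs edgeR called 0 genes, with 1434 at an unadjusted p under 0.05, 72 by DESeq2 and 166 by limma-voom, and between 8 and 10 without IZ or BZ replicate 2 or 3 (9, 9, 10 and 8). The macrophage list was higher in Young Late IZ than in BZ, with 0 of 23 genes called over all genes (13 adjusted over the list alone), a median of 1.25 and a camera adjusted p = 1.09e-18 (0.455 estimated), and that median was 0.62 without IZ or BZ replicate 1.

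The change of the IZ response with time was tested as Late minus Early. In Young pigs the response of CILP was higher at 1 week by 5.69 ± 0.68, of the lipid carrier APOE by 5.23 ± 0.93 and of ACTA1 by 3.08 ± 0.49. In Young shams CILP changed by −1.98 and ACTA1 by −1.95, and sham changes may hold part of the other differences too. Responses were lower for HSPA5 at −1.98 ± 0.34, MYC at −2.64 ± 0.50, PDGFRA at −4.14 ± 0.90 and TNFRSF11B at −6.12 ± 1.21. All 7 are among the 20 of 44 named called genes whose call held in all 12 fits without 1 library. With 23 macrophage genes measured, 12 had a higher response at 1 week (15 adjusted over the list alone), with a median of 2.33 and a camera adjusted p = 1.21e-12 (0.382 estimated). Among 35 extracellular matrix genes, 14 had a higher and 1 a lower response (17 and 1 adjusted over the list alone), with a median of 1.15 and a camera adjusted p = 3.55e-07 (0.435 estimated). With 36 nuclear oxidative phosphorylation genes measured, 7 had a higher response (11 adjusted over the list alone). Their median was 0.87, with a camera adjusted p = 1.65e-07 (0.482 estimated). Of 18 hypoxia genes 6 had a lower response (10 adjusted over the list alone), with a median of −1.10 and a camera adjusted p = 0.000243 (0.382 estimated). With 38 cell cycle genes measured, 3 had a higher and 1 a lower response (0 adjusted over the list alone), with a median of 0.93 and a camera adjusted p = 0.00101 (0.6 estimated). That median was 0.57 (camera adjusted p = 0.0896) without Young Late Sham replicate 3 and 1.61 without Young Late Sham replicate 1. edgeR called 1792 genes, 890 higher and 902 lower (1160 by limma-voom, 599 with RNA integrity as a covariate, 3118 on the compared groups alone). The count was 1086 and 1000 without Young Early Sham replicates 1 and 3, 848 and 858 without Young Early IZ replicates 1 and 3, 2691, 677 and 1108 without Young Late Sham replicates 1, 2 and 3, and 996 and 968 without Young Late IZ replicates 1 and 2. Of 100 regroupings only the real one gave as many.

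In Old pigs the response of COL11A1 was higher at 1 week by 7.54 ± 1.03, that of the growth factor PTN by 5.18 ± 0.63, that of APOE by 4.62 ± 0.92, that of CTHRC1 by 4.44 ± 0.91 and that of CILP by 4.06 ± 0.64. The response of FLT1 was lower at −2.14 ± 0.38. Sham changes may hold part of these 6 differences too. All 6 are among the 20 of 32 named called genes whose call held in all 12 fits without 1 library. With 35 extracellular matrix genes measured, 19 had a higher response (23 higher and 1 lower adjusted over the list alone). Their median was 2.15, or 2.13 with absent members at their bound, with a camera adjusted p = 6.6e-27 that held with an estimated correlation (0.0211). Of 19 fibroblast genes 9 had a higher response (11 adjusted over the list alone), with a median of 1.46 and a camera adjusted p = 4.48e-14 that held too (0.0211). Among 14 endothelial genes, 9 had a lower response (12 adjusted over the list alone), with a median of −1.35 and a camera adjusted p = 2.92e-12 that also held (0.0211). Of 23 macrophage genes 8 had a higher response (16 adjusted over the list alone). Their median was 1.87, with a camera adjusted p = 4.59e-13 (0.135 estimated). With 22 interferon response genes measured, 9 had a higher response (16 adjusted over the list alone), with a median of 2.22, or 1.011 without Old Early Sham replicate 3, and a camera adjusted p = 1.03e-09 (0.347 estimated). The cell cycle list had 0 of 38 genes called (0 adjusted over the list alone), a median of 0.98, or 1.58 without Old Late Sham replicate 2, and a camera adjusted p = 7.93e-06 (0.434 estimated). edgeR called 659 genes, 428 higher and 231 lower (523 by limma-voom), against 430 and 422 without Old Late Sham replicates 1 and 3, 270 without Old Early Sham replicate 3 and 438 without Old Late IZ replicate 3. Of 100 regroupings only the real one gave as many.

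The sham groups show what differs with age without an infarct, although Early shams of the 2 ages lie in preparation batches 1 and 2, and Old Late shams in batch 3. In Early shams RSAD2 was higher in Old than in Young pigs by 5.93 ± 1.08 (3.74 without Old Early Sham replicate 3), TOP2A by 1.47 ± 0.39 and the chaperone DNAJB9 by 1.41 ± 0.24, while the glycolytic enzyme PFKL was lower at −1.59 ± 0.25, with all 3 libraries of 1 age on 1 side of the other in these 4 genes. Of 22 interferon response genes 20 were higher (21 adjusted over the list alone), with a median of 2.13, or 1.02 without Old Early Sham replicate 3, and a camera adjusted p = 3.76e-07 (0.914 estimated). Of 38 cell cycle genes 12 were higher (12 adjusted over the list alone). Their median was 0.65, with a camera adjusted p = 0.00385 (0.914 estimated), but 0.52 and a camera adjusted p = 0.0807 without Young Early Sham replicate 3. Of 36 nuclear oxidative phosphorylation genes 11 were lower (11 adjusted over the list alone), with a median of −0.55 and a camera adjusted p = 0.000235 (0.914 estimated). edgeR called 4516 genes, 2540 higher and 1976 lower in Old pigs, against 2090 and 2862 without Young Early Sham replicates 1 and 3 and 2096 without Old Early Sham replicate 3, 1400 with preparation batch as a term and 1403 with RNA integrity as a covariate (mean 7.37 in Old and 6.7 in Young Early shams). Of 53 named called genes 30 kept the call without each of the 6 libraries. In Late shams ACTA1 was higher in Old pigs by 1.63 ± 0.34 and PPARGC1A by 1.22 ± 0.29, which were 2 of the 9 of 37 named called genes whose call held. edgeR called 1583 genes in Late shams, 1014 higher and 569 lower in Old pigs, against 669 and 803 without Young Late Sham replicates 1 and 2 and 606 and 387 without Old Late Sham replicates 1 and 2. It called 2789 with sex as a term, 2425 on the compared groups alone, 133 with RNA integrity as a covariate, and 768 higher and 695 lower without mitochondrially encoded genes. Old and Young Late shams differed in RNA integrity (mean 8.07 and 7.13) and in mitochondrial counts (23.4% and 38.1%), so quality and age are not separated there.

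Between 3 and 9 days of age, Young shams had lower ACTA1 at −1.95 ± 0.35, the fatty acid carrier FABP4 at −2.15 ± 0.37, the growth factor IGF1 at −2.96 ± 0.60 and SOX18 at −1.48 ± 0.29, with all 3 Late libraries below all 3 Early ones. Among 23 macrophage genes, 6 were lower (11 adjusted over the list alone), with a median of −1.10 and a camera adjusted p = 3.02e-05 (0.61 estimated). Among 38 cell cycle genes, 7 were higher (7 adjusted over the list alone). Their median was 0.79, with a camera adjusted p = 3.02e-05 (0.635 estimated), but 0.01 and a camera adjusted p = 0.567 without Young Late Sham replicate 1. edgeR called 1271 genes, 637 higher and 634 lower, against 397, 535 and 340 without Young Early Sham replicates 1, 2 and 3 and 1927, 208 and 571 without Young Late Sham replicates 1, 2 and 3, 597 with RNA integrity as a covariate, 584 by limma-voom, 2041 by DESeq2, 327 with sex as a term and 698 with batch as a term. All Young Early shams lie in batch 1 and 2 of 3 Young Late shams in batch 2. Among 39 named called genes, 13 kept the call without each of the 6 libraries. Against Early shams, Old Late shams had 4 genes called by edgeR. SUN2 was higher by 1.47 ± 0.26 and the amino acid enzymes GCDH and ALDH4A1 by 1.20 ± 0.20 and 0.94 ± 0.18. GSTA4 was lower at −1.39 ± 0.24. Of these calls 0 held without each of the 6 libraries, and the count was 10 without Old Late Sham replicate 1, 8 and 11 without Old Early Sham replicates 1 and 2, and 0 without Old Late Sham replicate 2 or 3 or Old Early Sham replicate 3. It was 106 by DESeq2, 950 on the compared groups alone and 0 with RNA integrity as a covariate (915 at an unadjusted p under 0.05).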

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

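The tests of the 3 patterns weighed here and the regroupings of comparisons between 2 groups were chosen after the results were seen, while the regroupings of the 6 differences between responses were planned before theirs were.

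Each value given here is a difference between 2 responses to infarction, in hearts of different age or at different times, tested on the difference itself. Gene values passed in edgeR and list medians passed camera at a preset correlation of 0.01, which most lists did not do with a correlation estimated from the data. For the Early IZ response, Old minus Young, edgeR called 133 genes, a count that moved by over 1.5 times without any 1 of the 12 libraries (0 to 1487) and was 0 by limma-voom with the animal as a random block (3581 at an unadjusted p under 0.05) and 934 by DESeq2. The log2 differences were 3.80 for ACKR1, 2.48 for TSPAN15, 1.90 for SOX18, 1.89 for ENG, −1.79 for IFIT5 and −2.98 for PDE3A, and each of these calls was kept only without Young Early IZ replicate 2 or Old Early IZ replicate 2, and lost without any 1 of the other 10 libraries. Shams alone differed by 1.98 for IFIT5 and 2.69 for PDE3A. List medians were 0.79 for endothelium (0.43 without Old Early IZ replicate 3), 0.62 for extracellular matrix, −1.66 for the interferon response (−0.64 and no longer called without Old Early Sham replicate 3) and −0.66 for the cell cycle (−0.40 and −0.52, no longer called, without Young Early IZ replicate 3 and Young Early Sham replicate 3). With an estimated correlation all 4 list calls were lost (adjusted p = 0.66, 0.685, 0.685 and 0.722).

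For the Late IZ response, Old minus Young, edgeR called 533 genes. This was 124 and 43 without Young Late IZ replicates 2 and 3, 84 without Young Late Sham replicate 2, 176 and 87 without Old Late IZ replicates 1 and 3, and 173 and 159 without Old Late Sham replicates 1 and 2. The log2 differences were 3.07 for SYTL2, −2.23 for CKMT2, −2.31 for RRAGD and −2.65 for ACTA1, whose calls held without each library, −2.03 for PPARGC1A, lost without Old Late IZ replicate 3, and 5.29 for FN1, lost without Old Late IZ replicate 3, Old Late Sham replicate 1 or 2, Young Late IZ replicate 2 or 3, or Young Late Sham replicate 2. List medians were 1.57 for extracellular matrix, 1.09 for fibroblasts, −1.15 for nuclear oxidative phosphorylation, −1.001 for the sarcomere and −0.51 for the cell cycle. With an estimated correlation all 5 list calls were lost (adjusted p = 0.135, 0.135, 0.151, 0.135 and 0.723). The cell cycle median was 0.10, −0.17 and −0.24, no longer called, without Old Late Sham replicate 2, Young Late Sham replicate 3 and Old Late IZ replicate 2, and −1.40, −0.82, −0.30 and −0.31 without Young Late Sham replicate 1, Old Late Sham replicate 3, Young Late IZ replicate 1 and Young Late Sham replicate 2.

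For the Early BZ response, Old minus Young, edgeR called 32 genes, a count that moved by over 1.5 times without any library but Young Early Sham replicate 2 and Old Early BZ replicate 3 (0 to 2256) and was 19 by limma-voom. The log2 differences were 1.94 for SOX18, lost without 9 of 12 libraries (all but Young Early BZ replicate 2, Young Early Sham replicate 2 and Old Early BZ replicate 3), and −2.12 for CORIN, lost without Old Early BZ replicate 1 or 2, Old Early Sham replicate 2 or 3, or Young Early Sham replicate 1. List medians were 0.97 for extracellular matrix, 0.88 for endothelium, 1.20 for macrophages and −0.58 for nuclear oxidative phosphorylation (−0.12 and no longer called without Young Early BZ replicate 2, −0.39 without Old Early BZ replicate 3). With an estimated correlation all 4 list calls were lost (adjusted p = 0.308, 0.266, 0.347 and 0.561), and edgeR called 0 matrix, macrophage and oxidative phosphorylation genes over all genes (12, 1 and 2 adjusted over each list alone). For the Late BZ response, Old minus Young, edgeR called 158 genes, a count that moved by over 1.5 times without any library but Young Late Sham replicate 1, Old Late BZ replicate 2 and Old Late BZ replicate 3 (0 to 388) and was 4 by limma-voom. The log2 differences were 2.16 for MMP2, 2.14 for LOXL1 and 2.23 for ACTA2, all lost without Old Late BZ replicate 1, Old Late Sham replicate 1, 2 or 3, Young Late BZ replicate 1 or 3, or Young Late Sham replicate 2. List medians were 1.49 for extracellular matrix, 1.25 for fibroblasts, −0.55 for nuclear oxidative phosphorylation and −0.69 for the cell cycle (−0.02 and −0.30, no longer called, without Old Late Sham replicate 2 and Young Late Sham replicate 3, and −1.35 without Young Late Sham replicate 1). With an estimated correlation these 4 list calls were lost (adjusted p = 0.105, 0.105, 0.657 and 0.751).

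For the IZ response of Young pigs, Late minus Early, edgeR called 1792 genes. This was 1086 and 1000 without Young Early Sham replicates 1 and 3, 848 and 858 without Young Early IZ replicates 1 and 3, 2691, 677 and 1108 without Young Late Sham replicates 1, 2 and 3, and 996 and 968 without Young Late IZ replicates 1 and 2. The log2 differences were 5.69 for CILP, 5.23 for APOE, 3.08 for ACTA1, −1.98 for HSPA5, −2.64 for MYC, −4.14 for PDGFRA and −6.12 for TNFRSF11B. List medians were 2.33 for macrophages, 1.15 for extracellular matrix, 0.87 for nuclear oxidative phosphorylation, −1.10 for hypoxia and 0.93 for the cell cycle (0.57 and no longer called without Young Late Sham replicate 3, 1.61 without Young Late Sham replicate 1). With an estimated correlation all 5 list calls were lost (adjusted p = 0.382, 0.435, 0.482, 0.382 and 0.6). For the IZ response of Old pigs, Late minus Early, edgeR called 659 genes, against 430 and 422 without Old Late Sham replicates 1 and 3, 270 without Old Early Sham replicate 3 and 438 without Old Late IZ replicate 3. The log2 differences were 7.54 for COL11A1, 5.18 for PTN, 4.62 for APOE, 4.44 for CTHRC1, 4.06 for CILP and −2.14 for FLT1. List medians were 2.15 for extracellular matrix, 1.46 for fibroblasts, −1.35 for endothelium, 1.87 for macrophages, 2.22 for the interferon response (1.011 without Old Early Sham replicate 3) and 0.98 for the cell cycle (1.58 without Old Late Sham replicate 2). With an estimated correlation the calls of the first 3 held (adjusted p = 0.0211 each), and those of macrophages, the interferon response and the cell cycle were lost (0.135, 0.347 and 0.434).

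For each difference between responses, 100 of 200 regroupings were fitted, in which the infarcted and the sham libraries were each parted anew, so that an age or time difference shared by both can appear as a difference between responses. For Old minus Young, as many called genes came from 8 of 100 regroupings for the Early IZ (133 against a highest other of 4895), 6 for the Late IZ (533 against 2576), 16 for the Early BZ (32 against 6853) and 5 for the Late BZ (158 against 608), the real one included. Chance is not excluded for these 4 counts, and the regroupings that call several times the real count point to a structure of the samples. For Late minus Early, 1 of 100 gave as many in Young (1792 against 1387) and Old pigs (659 against 622). Regroupings mix times, adding spread, so chance stays open.

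Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. For IZ against sham the real count and the highest of the other splits were 3956 and 0 in Young Early, 4988 and 24 in Old Early, 4390 and 4 in Young Late, and 7137 and 0 in Old Late pigs, with 1 split as large in each. For BZ against sham they were 162 and 2785 in Young Early, with 3 splits as large, and 3275 and 0, 2071 and 9, and 5775 and 0 in Old Early, Young Late and Old Late, with 1 each. The split with 2785 sets Young Early BZ replicates 1 and 3 and Sham replicate 2 apart from the rest, which points to a structure of the samples. For shams they were 4516 and 2 (Old against Young, Early), 1583 and 75 (Late), 1271 and 2 (Late against Early, Young), with 1 each, and 4 and 9 (Old), with 2. IZ against BZ allows 4 splits, also too few, with 1541 and 0 in Young Early and 295 and 0 in Old Late (1 as large), 0 and 0 in Old Early and 0 and 1 in Young Late (4 as large).

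Interferon response genes such as RSAD2 were higher in Old Early than in Young Early shams, by a list median of 2.13, a list call that was lost with an estimated correlation (adjusted p = 0.914), although 20 of 22 members were called. Without Old Early Sham replicate 3 the median was 1.02, which argues against that library as the whole source. Still, the 3 Old Early shams lay at 4.03, 2.37 and 5.76 log2 CPM, and the second lay among the Young Early libraries. Batch 2 libraries exceeded batch 1 libraries within the 3 Young Late groups by 0.488 ± 0.312 (SE over those groups), and medians of 0.12 for macrophages and 0.29 for lymphocytes argue against more leukocytes. Batch as a part of the shift, an immune stimulus in some pigs and age, told from batch only by Young Late, remain open.

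In the Late IZ, 13 of 36 nuclear oxidative phosphorylation genes had a lower and 7 of 35 matrix genes a higher response in Old pigs, and both list calls were lost with an estimated correlation (adjusted p = 0.151 and 0.135). A uniformly lower share of cardiomyocytes would raise the genes of other cells alike. Yet the fibroblast mean exceeded the macrophage mean by 1.19 ± 0.291 (SE over genes, not pigs). With mitochondrially encoded genes left out of the scale, the nuclear oxidative phosphorylation median was −1.03 and passed at the preset correlation. Batch 3 held 0 libraries outside Old Late. A batch effect unlike in IZ and sham cannot be told apart from age, while one shared by both cancels. Fewer cardiomyocytes with more fibroblasts, and metabolic gene loss with fibroblast activation in older hearts, stay open and were not tested apart.

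Few genes passed in the Early BZ difference by age, and 2256 passed without Young Early BZ replicate 2, against at most 53 without another library, so that the spread from this library may hide a difference. Its total of 39.8 M counts argues against low depth. Its deviations correlated at 0.6 with the IZ of its own pig and at −0.38 or less with that of the others. On 100 genes that separate pigs it lay at 1.007 from the IZ of its own pig and at 1.785 and 1.972 from those of the others, which argues against a library from another infarcted pig of the group. Nor did it lie near the shams of its group, with 10.1% mitochondrial counts (shams 27.1 to 44.1, the other BZ libraries 26.3 and 29.9), 0.2 on the first principal component (shams −53.3 to −41.6, the other BZ libraries −33.6 and −11.5) and 144.6 on the second (shams 45.1 to 59.3). What sets this library apart remains open, and no biological difference between ages was established here.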

How the results depend on the processing

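A term for sex and the fit without Young Early BZ replicate 2 and Young Late Sham replicate 2 were chosen after seeing the data. Across 22 counts of called genes and their alternatives, 230 values stayed within 1.5 times and 181 did not. Of values for named genes 18621 kept their side of the threshold, 182 gained a call and 2620 lost it, and of values for lists these numbers were 10373, 223 and 467, with 9 reversed. DESeq2 size factors and leaving out mitochondrially encoded genes kept all 22 counts within 1.5 times, although without those genes the higher and lower genes numbered 253 and 169 of 422 in the Late IZ and 166 and 33 of 199 in the Late BZ difference by age, and 768 and 695 of 1463 between Late shams by age, and each of the 2 gave 3 and 3 for Old shams by time. Without those genes, and in a fit of the compared groups alone, the median of all genes moved by 0.12 in the Late IZ difference by age. The DESeq2 test gave 561 (334 higher, 227 lower) for BZ against sham in Young Early, 2567, 4, 72 and 1011 for IZ against BZ in Young Early, Old Early, Young Late and Old Late (322 higher, 689 lower), 934 and 1061 (507 higher, 554 lower) for the Early and Late IZ and 602 (297 higher, 305 lower) and 592 for the Early and Late BZ difference by age, and 2041 and 106 (62 higher, 44 lower) for Young and Old shams by time. Without a filter on counts, edgeR gave 58 for BZ against sham in Young Early, 5 and 285 for the Early and Late IZ and 26 for the Late BZ difference by age, and 11 for IZ against BZ in Young Late. A fit of the compared groups alone, with fewer residual degrees of freedom, gave 0 for BZ against sham in Young Early, 0 and 1733 for IZ against BZ in Young Early and Old Late, 1444 and 800 for the Early and Late IZ and 0 and 45 for the Early and Late BZ difference by age, 3118 for Young IZ by time, 2425 for Late shams by age and 950 for Old shams by time. Batch as a term gave 5 for the Early IZ difference by age, 1400 for Early shams by age and 698 for Young shams by time. RNA integrity as a covariate gave 27 and 3609 for BZ against sham in Young Early and Old Late, 0 for the Early IZ and 0 and 18 for the Early and Late BZ difference by age, 599 for Young IZ by time, 1403 and 133 for Early and Late shams by age, and 597 and 0 for Young and Old shams by time, and reversed the macrophage (0.18), endothelium (−0.25) and mitochondrially encoded (−0.93) medians of IZ against BZ in Old Early. A minimum log2 fold change of 1, which can only remove genes, gave 2399, 3121 and 2840 for IZ against sham in Young Early, Old Early and Young Late, 99, 2018, 1287 and 3729 for BZ against sham in Young Early, Old Early, Young Late and Old Late, 750 and 161 for IZ against BZ in Young Early and Old Late, 2434 and 905 for Early and Late shams by age and 798 for Young shams by time. The limma-voom fit with the animal as a random replicate block (consensus correlation 0.378) gave 22 and 1372 for BZ against sham in Young Early and Young Late, 3365, 1, 166 and 1295 for IZ against BZ in Young Early, Old Early, Young Late and Old Late, 0 for the Early IZ and 19 and 4 for the Early and Late BZ difference by age, 1160 for Young IZ by time and 584 for Young shams by time. With no replicate block, IZ against BZ gave 355, 1 and 5 in Young Early, Old Early and Old Late, and with the other animal label the replicate block gave 0 in Old Late. Sex as a term gave 303 for the Early IZ and 392 for the Late BZ difference by age, 2789 for Late shams by age, and 327 and 7 for Young and Old shams by time. Leaving out both doubtful libraries gave 2429 for the Early IZ and 2404 and 63 for the Early and Late BZ difference by age, 1153 for Old IZ by time, 2378 for Late shams by age, 64 for Old shams by time, and 330, 3 and 1559 for IZ against BZ in Young Early, Young Late and Old Late, and reversed the mitochondrially encoded median of IZ against BZ in Young Early (−0.68). Leaving out 1 library at a time, where a lone or paired remainder is assumed to vary like the other groups, gave 2304 to 3892, 3258 to 5413, 2807 to 4428 and 5845 to 6931 for IZ against sham in Young Early, Old Early, Young Late and Old Late, and 11 to 979, 1967 to 2690, 694 to 2566 and 3508 to 5445 for BZ against sham in that order. It gave 321 to 1548, 0 to 14, 0 to 10 and 0 to 0 for IZ against BZ in that order, 0 to 1487 and 43 to 752 for the Early and Late IZ and 0 to 2256 and 0 to 388 for the Early and Late BZ difference by age, 677 to 2691 and 270 to 644 for Young and Old IZ by time, 2090 to 3659 and 387 to 1463 for Early and Late shams by age, and 208 to 1927 and 0 to 11 for Young and Old shams by time. It reversed the mitochondrially encoded median of IZ against BZ in Young Early without IZ or BZ replicate 2 (range −0.6825 to 0.8361), the endothelium median of IZ against BZ in Old Early without IZ or BZ replicate 3 (range −0.1666 to 0.3119) and the interferon response median of Old shams by time without Old Early Sham replicate 3 (range −1.444 to 0.2412). Except where fewer samples or a stricter threshold explain it, the cause was not tested.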

Other observations

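Other gene groups moved in the IZ besides those of the main comparisons. In Young Early IZ the immediate early gene FOS rose by 3.72 ± 0.45 against sham (log2, SE, n = 3 per group), and of 19 immediate early genes 10 rose and 1 fell by edgeR (11 and 1 adjusted over the list alone), with a median of 1.33 and a camera adjusted p = 2.13e-05 (0.0614 estimated). Of 8 adipocyte genes 4 fell there (5 adjusted over the list alone), with a median of −1.29 and a camera adjusted p = 0.00361 (0.134 estimated). In Young Late IZ the intercalated disc gene XIRP2 rose by 4.42 ± 0.91, and of 10 cardiac stress genes 7 rose (7 adjusted over the list alone), with a median of 1.84 and a camera adjusted p = 0.00372 (0.22 estimated). In Old Late IZ the potassium channel gene KCNJ2 fell by 2.75 ± 0.38, and of 18 cardiac channel and transcription factor genes 16 fell (16 adjusted over the list alone), with a median of −1.46 and a camera adjusted p = 1e-07 (0.108 estimated). The killer cell gene NKG7 rose by 4.28 ± 0.52, and of 17 lymphocyte genes 11 rose (12 adjusted over the list alone), with a median of 1.39 and a camera adjusted p = 0.0147 (0.26 estimated). The epicardial factor TBX18 rose by 2.66 ± 0.38, and of 6 epicardium genes 4 rose (4 adjusted over the list alone), with a median of 2.14 and a camera adjusted p = 0.0147 (0.0734 estimated). For each of these 5 genes the 3 IZ libraries lay on 1 side of the 3 shams.

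Some lists did not pass as groups in Old Late IZ. Of 19 glycolysis genes 5 rose and 6 fell, with a median of −0.28, a mean of 0.16 and a downward camera test, while LDHA rose by 2.23 ± 0.47. Of 13 YAP and neuregulin genes 3 rose and 6 fell, with a median of −0.33, a mean of 0.21 and a downward test. Of 9 fetal growth genes 1 rose, the imprinted gene MEST by 2.44 ± 0.43, and 3 fell, with a median of −0.73. Of 8 atrium genes 5 rose and 1 fell, with a median of 1.25, and of 9 Schwann cell genes 1 rose and 2 fell, with a median of 0.02, a mean of −0.17 and a downward test. Of 5 red blood cell genes 0 were called by edgeR, with a median of −1.09. In Old Early IZ 3 of 6 skeletal muscle genes rose, with a median of 1.32, and 5 of 11 smooth muscle genes rose, with a median of 0.61, and neither list passed.

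The calls for IZ against sham were set beside one another for the 2 ages, which share no pigs. Early after injury 2207 genes were higher in Young and 2838 in Old pigs, and 1189 of these were shared, against 431 if the calls were independent. For genes that were lower the numbers were 1749, 2150 and 796, against 259. At 1 week 1953 of 2499 and 3646 higher genes were shared, against 627, and 1288 of 1891 and 3491 lower genes, against 454.

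Deviations of the 3 Young Late zone pairs did not correlate (−0.2 to −0.04), unlike the other 9 (0.45 to 0.67). All 12 sex readings matched, but only Young Late replicates 1 and 3 spanned 2 batches. For Old Late BZ replicate 3 the labels give 2 animal numbers, and no other library carries the second. Its deviations correlated at 0.67 with the IZ of the pig in its title and at −0.19 and −0.47 with the IZ of the other 2 pigs, which favors the title. On 100 genes that separate pigs its distances to these IZ libraries were 0.441, 0.467 and 0.828, and 8 of 12 BZ libraries lay nearest the IZ of their own pig (4 by chance).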
